A study of Escherichia coli with 4 samples.

How the data were processed

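Total RNA from Escherichia coli K-12 MG1655, the standard laboratory wild type, was compared between biofilm (surface-attached) and planktonic (suspended) cells taken from serine-limited chemostats, vessels in which a steady feed of fresh medium sets the growth rate. The 4 arrays formed 2 groups of 2: biofilm arrays numbered 8 and 9 and planktonic arrays numbered 8 and 9. Groups and numbers were taken from the sample titles. The labels gave a culture time of 4 or 6 days for the series as a whole, without saying which array had which. The labels called the cultures duplicate but did not say what a shared number marked, so p-values measured only the spread between these arrays.

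Per the labels, RNA was reverse transcribed into cDNA carrying radioactive CTP, and each array held 1 channel. The deposited table gave 1 normalized intensity per probe and array on a linear scale, with 4290 probes. The titles called the values normalized, and the method, the background correction and the treatment of duplicate spots were not given in the sources used here. The total intensity per array lay between 123397 and 123581, a largest difference of 0.149%, so each array appeared scaled to a common total. The median intensity was 19.8 and 18.4 on biofilm arrays 8 and 9, and 17.5 and 17.6 on planktonic arrays 8 and 9. No value was 0 or below. The number of arrays limited the precision.

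Genes were named through the platform annotation. Of the probes, 4095 had 1 symbol, 0 had several and 195 had none. The unnamed probes were left out, and carried 3.70 to 4.30% of the signal of an array. Of the symbols, 4094 matched the table of genes of the MG1655 assembly ASM584v2, which supplied coding lengths. No genome build was named for the arrays, so no positions are given.

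Intensities were turned to log2 with no floor, pseudocount or further normalization. Differences were tested with limma 3.58.1 (lmFit, and eBayes with a prior variance that followed the mean level) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 4095 named genes and a threshold of 0.05. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 35 lists with at least 3 measured members, beside camera with an estimated correlation and fry, a rotation test. The lists held 807 entries written from textbook knowledge, of which 788 were measured. Another count, without a test, took the genes whose biofilm intensity was at least 2 times the planktonic one, or the reverse, both between the arrays numbered 8 and between those numbered 9. Means are given with the SD over the arrays of a group, and log2 differences with the SE of the fit.

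The named genes followed a rule. It took, per direction, the 12 genes with the largest change among those that passed, filled with those of smallest unadjusted p where fewer passed, and left out genes with both group means below the 25th percentile of levels. It added up to 4 members of smallest p from each described list. It also added serA, serB, serC, glyA, sdaA, sdaB, sdaC, csgA, csgD, fimA, flu, fliC, bssR and rpoS whatever their result. The tests, lists, rule and most alternatives were fixed before the data were examined.

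Further choices were made after the data were examined. In blocks of 96 consecutive probes, each array's Pearson correlation of log2 values with each other array was computed, and a block was called discordant for an array whose highest such correlation was under 0.9. Results were recomputed without the genes of discordant blocks, and with the values concerned set to missing. A trend of each array's deviation from the probe mean on coding length and level was also removed, by loess with a span of 0.4. The rule for the 12 genes per direction was applied again to genes outside discordant blocks. The alternatives fixed beforehand were quantile, median, 75th percentile and cyclic loess normalization, a floor or pseudocount at the 10th percentile, filters at the 25th and 50th percentile of levels, other variance models, the array number as a covariate, other thresholds, and leaving out each array.

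The fits were tested on simulated arrays with the spread of the real ones and 200 genes changed by a known fold. Over all 4095 named genes, 0% of 2-fold changes and 72% of 4-fold changes passed. Over the 2824 genes outside discordant blocks, 57% and 94% passed. The simulated noise was independent between genes and held no discordant blocks and no trend on level or length. These rates therefore need not hold for the real arrays. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.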

Results

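The series compared the transcripts of biofilm and planktonic E. coli MG1655 on 4 membrane arrays, 2 per culture type, grown in minimal medium with serine as the limiting nutrient. Normalized intensities of 4095 named genes were compared. The log2 intensities of arrays correlated across genes with r between 0.849 (planktonic 8 with biofilm 9) and 0.949 (the planktonic arrays). In some probe blocks single arrays departed from all the others, as described after the comparisons. Outside these blocks biofilm 9 correlated at 0.969 with planktonic 8, 0.965 with biofilm 8 and 0.960 with planktonic 9, so it was as close to the planktonic arrays as to the other biofilm array. Biofilm 8 correlated at 0.914 and 0.907 with planktonic 8 and 9, and the planktonic arrays at 0.976 with each other.

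No named gene passed the threshold between biofilm and planktonic cultures in the comparison of all 4 arrays. Among the genes nearest to it on the biofilm side, intensities of pepN, aminopeptidase N, were 12.7 ± 3.68 in biofilm and 1.71 ± 0.0990 in planktonic cells (SD, n = 2 each), those of guaB, the IMP dehydrogenase of guanine nucleotide synthesis, were 17.1 ± 3.64 and 3.21 ± 0.431, and those of dadX, an alanine racemase, were 17.9 ± 0.771 and 6.47 ± 0.276. On the planktonic side stood borD, a prophage lipoprotein gene, with 3.47 ± 1.09 in biofilm and 13.99 ± 0.750 in planktonic cells, and zntR, the zinc-responsive regulator, with 30.02 ± 2.57 and 58.9 ± 14.3. Of the genes named in this paragraph only zntR had its probe outside discordant blocks, and that of dadX lay in a block discordant on both biofilm arrays. By limma with Benjamini-Hochberg adjustment the lowest adjusted p was 0.264, and 588 genes had an unadjusted p under 0.05, of which 510 were higher and 78 lower in biofilm. Without biofilm 8, 154 genes passed, against the lone biofilm array 9, and leaving out any other array gave 0.

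The 12 genes of smallest p on the biofilm side, none of which passed, were ydiO, pepN, guaB, ydeP, ydjJ, adhP, dadX, sufS, rutG, rlmC, yehQ and hflX. Their log2 differences ran from 1.47 for dadX to 4.07 for rutG, a pyrimidine permease gene with planktonic intensities of 0.890 ± 0.594 (SD, n = 2). The cysteine desulfurase gene sufS had a log2 difference of 3.15 ± 0.44 (SE), the alcohol dehydrogenase gene adhP 1.99 ± 0.25, and hflX, which encodes a ribosome-associated GTPase, 1.74 ± 0.25. The 12 on the planktonic side, none of which passed either, were borD, yiaT, wcaB, yafC, ortT, ycgN, zntR, ymfR, ycaR, bluF, flgN and melA, with log2 differences from -0.63 for flgN to -2.05 for borD. Of these, flgN encodes a chaperone of flagellar export, wcaB a colanic acid acetyltransferase and melA the alpha-galactosidase of melibiose use. Of the genes on the biofilm side, 11 lay in probe blocks where at least 1 array departed from all the others, as did 5 on the planktonic side. Among the former, ydiO, ydeP, ydjJ, adhP, dadX, sufS and rutG lay in the 2 blocks, with 190 named genes, that were discordant on both biofilm arrays.

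Serine degradation genes read higher in biofilm without passing. The serine deaminase gene sdaA had intensities of 15.02 ± 4.22 in biofilm and 5.86 ± 0.827 in planktonic cells (SD, n = 2 each), and its paralog sdaB 17.3 ± 7.47 and 8.23 ± 1.37. The serine transporter gene sdaC stood at 38.2 ± 1.84 and 31.7 ± 3.66. Among the synthesis genes, the log2 difference was 0.34 ± 0.23 (SE) for serA, -0.53 ± 0.21 for serB and 0.59 ± 0.23 for serC, and glyA, which interconverts serine and glycine, had -0.42 ± 0.36. In limma with Benjamini-Hochberg adjustment the adjusted p of these 7 genes ran from 0.264 for sdaA to 0.596 for glyA. The probes of serC, glyA and sdaA lay in discordant blocks, and serC read lower in biofilm once the level and length trend was removed.

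Of the adhesion and regulatory genes chosen beforehand, flu, which encodes the autoaggregation adhesin antigen 43, differed most, with 30.1 ± 7.07 in biofilm and 12.5 ± 0.396 in planktonic cells (SD, n = 2 each) and an adjusted p of 0.264 in limma with Benjamini-Hochberg adjustment. Its probe lay in a discordant block. The curli subunit gene csgA had 9.90 ± 0.453 and 9.99 ± 3.44, and csgD, the regulator of curli and cellulose, 11.98 ± 3.56 and 14.5 ± 5.33. The type 1 fimbrial subunit gene fimA stood at 2.76 ± 0.389 and 2.90 ± 1.67, and the flagellin gene fliC at 10 ± 0.580 and 8.08 ± 2.42. The biofilm regulator gene bssR had 31.6 ± 3.14 and 36.6 ± 3.43, and rpoS, which encodes the general stress sigma factor, 24.96 ± 4.37 and 19.6 ± 1.42. The directions of csgA, csgD, fimA and fliC changed with the scaling or the arrays used.

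**Figure D1:**
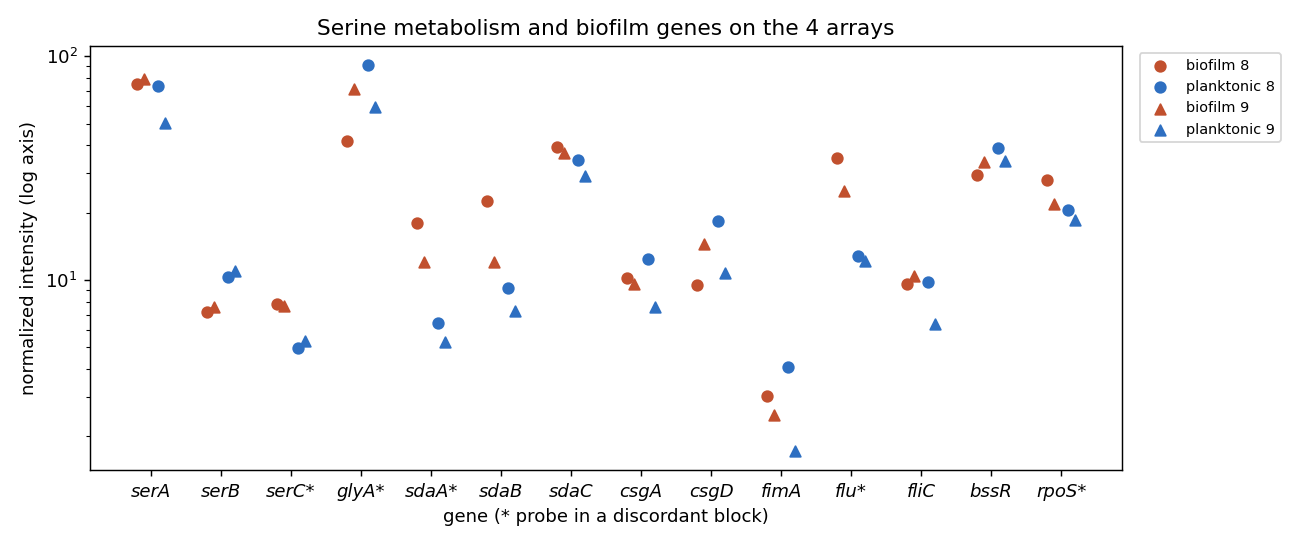
Normalized intensity (log axis) of the 14 serine metabolism and biofilm genes chosen beforehand, by gene, with 1 point per array: circles for arrays numbered 8, triangles for arrays numbered 9, red for biofilm, blue for planktonic, and asterisks for probes in discordant blocks. The points of serA, serC, sdaA, sdaB, sdaC, flu and rpoS lie higher on both biofilm arrays than on both planktonic arrays, those of serB and bssR lie lower, and those of glyA, csgA, csgD, fimA and fliC overlap.

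The gene lists asked whether pathways linked to biofilm growth or nutrient limitation differed together. None of the 35 lists passed camera with Benjamini-Hochberg adjustment, whose lowest adjusted p was 0.193. With an estimated correlation the lowest adjusted p was 0.957, and with fry it was 0.176. At an unadjusted p under 0.05, 6 lists stood apart from the other genes, and of all lists 30 had a median log2 difference above 0, against 0.10 over all named genes.

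Motility genes were among these 6. Of 41 flagellar genes, 32 read higher in biofilm and the median log2 difference was 0.47, with an unadjusted camera p of 0.0220 and an adjusted p of 0.193 after Benjamini-Hochberg adjustment (unadjusted p = 0.327 with an estimated correlation). Single members went both ways: flhA, part of the export apparatus, had a log2 difference of 1.49 ± 0.32 (SE), the hook gene flgE 1.42 ± 0.31 and flgJ 3.06 ± 0.65, against -0.63 ± 0.16 for flgN. Of 11 chemotaxis genes 8 read higher, with a median of 0.34 and an unadjusted camera p of 0.0409 (unadjusted p = 0.427 with an estimated correlation). The receptor genes trg and tar had 1.34 ± 0.36 and 0.75 ± 0.21, the methyltransferase gene cheR 1.26 ± 0.40 and the phosphatase gene cheZ 1.29 ± 0.42. No member of either list passed, also when adjusted over the list alone.

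Aerobic electron transport and ATP synthase genes read higher in biofilm for 21 of 28 members, with a median of 0.37 and an unadjusted camera p of 0.0372 (unadjusted p = 0.277 with an estimated correlation). Log2 differences were 2.14 ± 0.48 (SE) for nuoL and 1.07 ± 0.24 for nuoG, subunits of NADH dehydrogenase I, 1.36 ± 0.34 for cyoC of cytochrome bo oxidase and 1.03 ± 0.26 for atpD of the ATP synthase. The carbon source uptake list also held enzyme genes of sugar use, such as malQ and lacZ. Of its 46 genes 37 read higher, with a median of 0.27 and an unadjusted camera p of 0.0216 (unadjusted p = 0.499 with an estimated correlation). Among them malQ had 1.47 ± 0.40, lacZ 1.23 ± 0.39, araF 1.14 ± 0.38 and ptsG, which turned negative with the level and length trend removed, 0.78 ± 0.26. With that trend removed the log2 differences were 0.56 for malQ, 0.02 for lacZ and 0.32 for araF. Those of nuoL, nuoG, cyoC and atpD were then 0.92, 0.10, 0.69 and 0.44. No member of either list passed, also when adjusted over the list alone.

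Ribosome hibernation and starvation genes and genes of the prophages CP4-57 and e14 were the lists on the planktonic side. Of 9 hibernation and starvation genes 7 read lower in biofilm, with a median of -0.14 and an unadjusted camera p of 0.0171 (unadjusted p = 0.143 with an estimated correlation). Outside discordant blocks its 5 members had a median of -0.04 and an unadjusted camera p of 0.307. With the level and length trend also removed these were -0.24 and 0.0365. The carbon starvation gene cstA had a log2 difference of -1.22 ± 0.46 (SE), dksA -0.42 ± 0.18 and rmf, the ribosome modulation factor gene, -1.44 ± 0.88, against 0.31 ± 0.26 for uspA, whose sign turned under quantile and cyclic loess scaling. The rmf intensities were 195 ± 197 in biofilm and 370 ± 5.69 in planktonic cells (SD, n = 2 each), and the probes of rmf and cstA lay in discordant blocks. Of 26 prophage genes 16 read lower, with a median of -0.09 and an unadjusted camera p of 0.0127 (unadjusted p = 0.146 with an estimated correlation). The unadjusted camera p of this list was 0.0441 outside discordant blocks and 0.182 there with the level and length trend removed. Among these, ymfR had -0.98 ± 0.24, xisE -0.41 ± 0.19, yfjT -0.69 ± 0.33 and ymfM -0.76 ± 0.38, and the probes of ymfR, xisE and ymfM lay in discordant blocks.

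The surface structures linked to biofilms gave mixed values. Of 7 curli genes 4 read higher in biofilm, and the secretion gene csgG, with 4.37 ± 0.523 against 0.870 ± 0.269 (SD, n = 2 each), was the 1 gene that passed when adjusted over the list alone. The curli genes csgC, csgB and csgF had log2 differences of -0.74 ± 0.23 (SE), 1.35 ± 0.77 and 1.22 ± 0.76. Of 22 colanic acid genes, 12 read higher and 2 passed when adjusted over the list alone. These were gmd, with 8.18 ± 1.12 against 1.68 ± 0.0424, and wcaJ, with 13.7 ± 6.35 against 2.44 ± 0.325, while wcaB had a log2 difference of -0.70 ± 0.15 and wcaE 1.38 ± 0.36, and the probes of all 4 lay in discordant blocks. Of 9 type 1 fimbrial genes 7 read higher, with a median of 0.64, and the recombinase gene fimB had 2.21 ± 0.65, fimF 0.88 ± 0.39, fimG 0.70 ± 0.35 and the adhesin gene fimH 0.64 ± 0.33. Cellulose and PGA genes had a median of 0.36, with 0.86 ± 0.23 for bcsB, 0.92 ± 0.26 for bcsE, 0.52 ± 0.22 for bcsC and 0.80 ± 0.33 for pgaA. Of the 16 genes of AI-2 signalling and biofilm regulation 7 read higher, with 0.77 ± 0.18 for the transporter gene lsrC, 0.47 ± 0.23 for lsrD and -0.65 ± 0.28 for ariR. The probes of csgC, bcsB, pgaA and ariR likewise lay in discordant blocks. The signs of csgF, fimG, fimH, bcsC, pgaA and lsrD turned under at least 1 other scaling or with the trend removed.

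Genes of protein synthesis and stress likewise held few single differences. Of 54 ribosomal protein genes 27 read higher and 27 lower, with 1.45 ± 0.44 (SE) for rplJ, -1.17 ± 0.37 for rpmF, -0.69 ± 0.23 for rpsO and -0.64 ± 0.22 for rpmJ. Of 33 translation factor and tRNA synthetase genes 21 read higher, and 3 passed when adjusted over the list alone: valS with 2.19 ± 0.35, leuS with 1.45 ± 0.24 and proS with 1.28 ± 0.24, all in discordant blocks, beside glyS with 2.28 ± 0.50. Of 21 heat shock genes 16 read higher, with a median of 0.25 and log2 differences of 1.31 ± 0.23 for clpB, 1.30 ± 0.30 for dnaK, 1.87 ± 0.43 for dnaJ and 1.66 ± 0.40 for htpG. The general stress genes of RpoS had a median of 0.04, with 1.65 ± 0.30 for the trehalose gene otsB, 1.39 ± 0.28 for cfa, 0.83 ± 0.27 for the catalase gene katE and 1.15 ± 0.41 for osmY. In the list of serine, glycine and one-carbon metabolism 13 of 17 genes read higher, with 1.65 ± 0.33 for gcvP and 1.16 ± 0.41 for gcvT of glycine cleavage and 1.76 ± 0.52 for purU. Purine and pyrimidine genes were split, 11 higher and 10 lower, with guaB (2.40 ± 0.28), which passed when adjusted over the list alone, and purA (1.20 ± 0.42) against purC (-0.64 ± 0.18) and purK (-0.999 ± 0.289). Of the genes in this paragraph rplJ, rpmF, cfa, gcvP, gcvT, guaB and purA also had probes in discordant blocks.

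The other 18 lists had medians from -0.11 for histidine synthesis to 0.54 for aromatic amino acid synthesis, and 1 member, sufS of the oxidative stress list, whose probe lay in a discordant block, passed when adjusted over its list alone. The camera test, which compares a list with the other genes, pointed down while the median lay above 0 for the curli, colanic acid, methionine, purine and pyrimidine, RpoS, porin and toxin-antitoxin lists. The ribosomal protein list had a median just below 0 and a mean of 0.08.

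**Figure D2:**
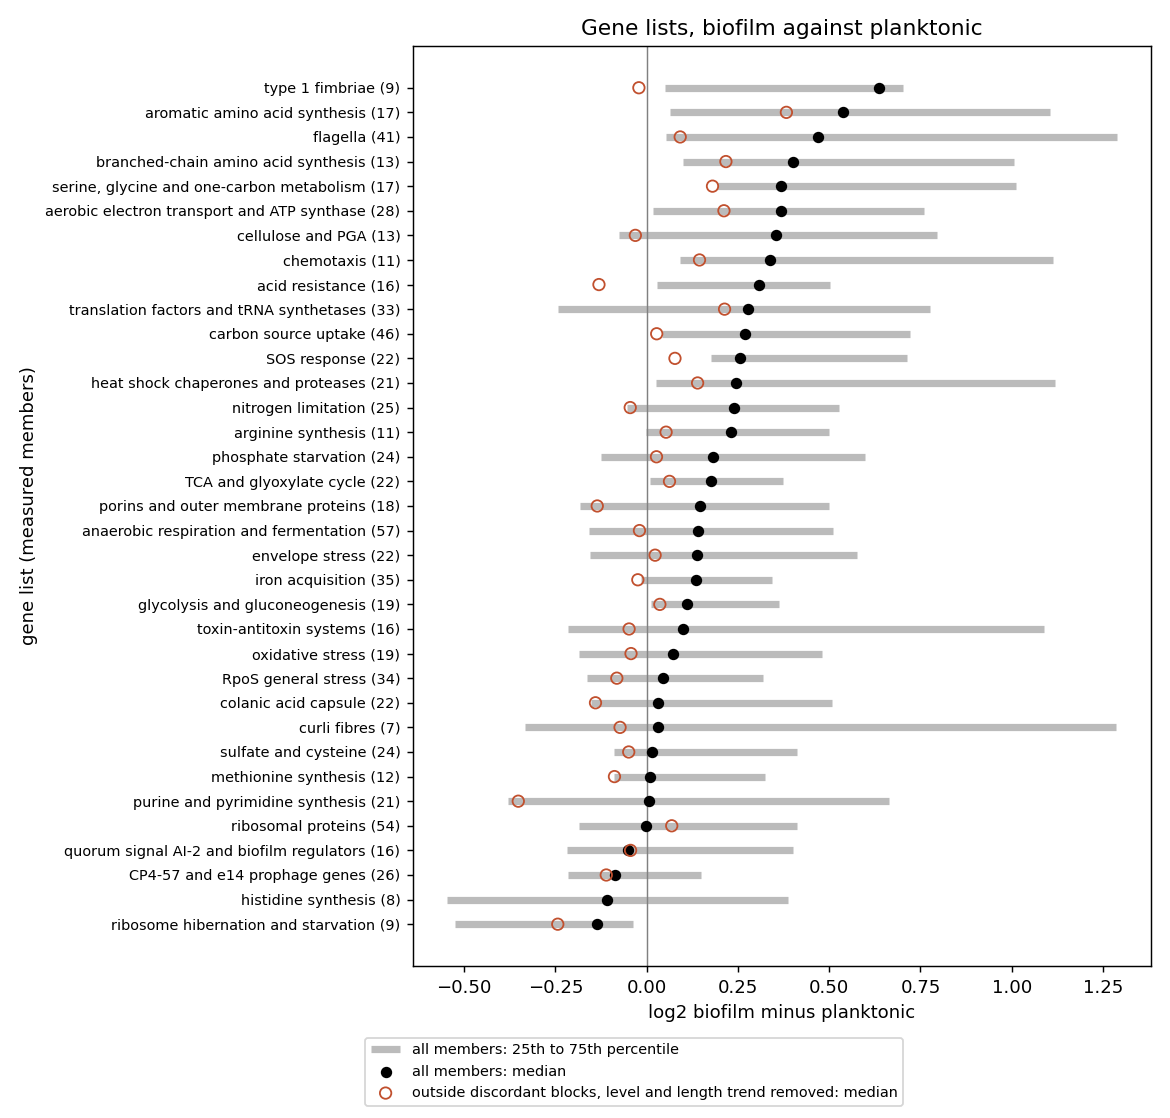
Log2 difference of biofilm minus planktonic (horizontal axis) for the 35 gene lists (vertical axis, with the number of measured members), as the median of all members (black points) and their 25th to 75th percentiles (grey bars); open red circles give the median outside discordant blocks with the level and length trend removed, which the histidine list has no members for. The black points lie above 0 for 30 lists, and the open circles for 16 of 34.

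The count of genes at least 2-fold apart the same way in both culture numbers needed no estimate of spread. It gave 253 genes, 246 higher and 7 lower in biofilm. Dividing the same arrays by number gave 9 genes, and the crossed division gave 5. Of the 253 genes, 216 had a mean level below the 25th percentile, and filtering on that percentile or removing the trend took the count to 37 and 68. The biofilm intensities lay both above or both below the planktonic ones for 51.6% of genes, against 33.3% expected for a gene if arrays were interchangeable. All genes share the same arrays, so the share can lie far from that without a difference between culture types.

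Agreement between arrays broke down in 14 blocks of 96 probes, a fact established after the data were examined. Biofilm 9 correlated with its best-matching array at 0.178 to 0.689 in 8 blocks, planktonic 8 at 0.768 to 0.879 in 6, and biofilm 8 at 0.745 to 0.865 in 2 that were also discordant on biofilm 9, while planktonic 9 had none. The median over the remaining blocks of an array was 0.965 to 0.974. These blocks held 1271 named genes, among them flu, rpoS, sdaA and most genes nearest to the threshold.

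**Figure D3:**
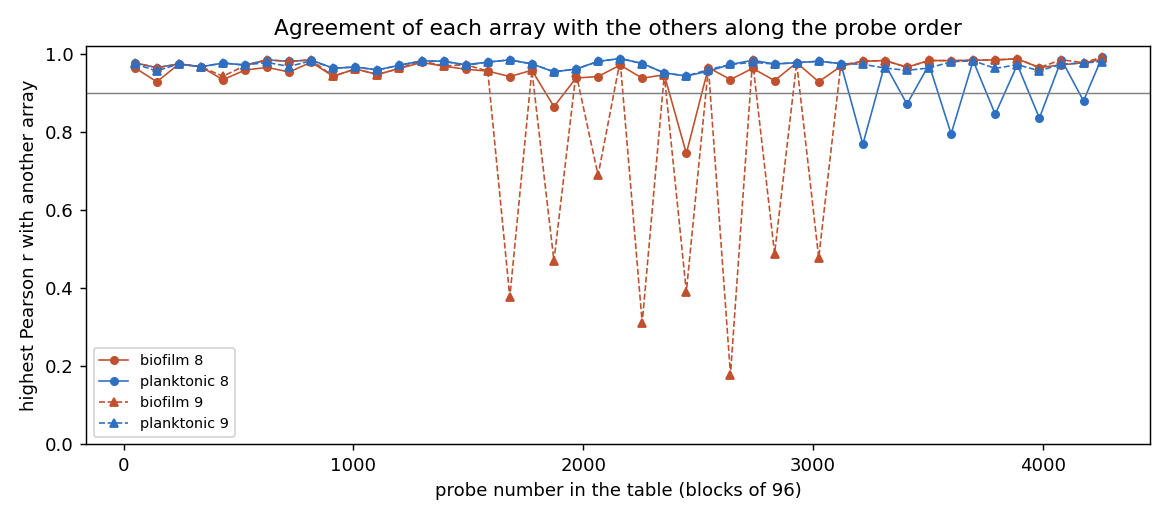
Highest Pearson correlation of log2 intensity with any other array (vertical axis) for each block of 96 probes by its position in the table (horizontal axis), 1 line per array, with the grey line at 0.9. Biofilm 9 falls to between 0.178 and 0.689 in 8 blocks and planktonic 8 to between 0.768 and 0.879 in 6.

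Among the 2824 genes outside these blocks, a selection made after the data were examined, 166 passed limma with Benjamini-Hochberg adjustment, 155 higher and 11 lower in biofilm, with a lowest adjusted p of 0.0116. Leaving out genes with both group means below the 25th percentile of levels, the 12 with the largest differences on the biofilm side were slyD, hycC, fdoG, thiC, insD5, mgtA, acrB, recE, yehQ, nuoL, insF2 and yajR, with log2 differences from 2.09 to 2.63. Dimmer genes that passed reached larger differences, up to 3.06 for flgJ. Intensities of the multidrug efflux gene acrB were 16.2 ± 6.37 in biofilm and 3.26 ± 0.693 in planktonic cells (SD, n = 2 each), those of the thiamine synthesis gene thiC 9.97 ± 5.11 and 1.69 ± 0.120, and those of slyD, a peptidyl-prolyl isomerase, 11.04 ± 4.58 and 1.71 ± 0.163. The probes of insD5 and insF2 belong to insertion sequences with near-identical copies, so their values are uncertain as single genes. The 11 lower genes were ortT, ogrK, purK, melA, ycaR, zntR, waaY, hypT, yiaT, yafC and flgN, with log2 differences from -0.63 for flgN to -1.10 for ortT. The same selection included 4 of 14 heat shock genes (clpB, dnaK, dnaJ and htpG) and 4 of 27 aerobic electron transport genes (nuoL, nuoG, cyoC and atpD). It also included 7 higher and 1 lower of 39 flagellar genes, beside 1 of 43 genes of the carbon uptake list. These shares were not tested against the 166 of 2824 overall. No list passed camera with Benjamini-Hochberg adjustment in this selection, where carbon uptake had the lowest unadjusted p, 0.00698, and an adjusted p of 0.118, and with an estimated correlation the lowest adjusted p was 0.895.

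These 166 calls did not hold under every treatment. Leaving out only the discordant blocks of biofilm 9 gave 0 of 3357 genes, with a lowest adjusted p of 0.175 by limma with Benjamini-Hochberg adjustment, so the calls appeared only once the blocks of planktonic 8 were left out as well. No gene passed outside the blocks after cyclic loess, quantile normalization or removal of the level and length trend. The lowest adjusted p by limma with Benjamini-Hochberg adjustment were 0.104, 0.235 and 0.221. All 166 kept their sign after trend removal, and 118 had an unadjusted p under 0.05 in limma, against 393 of all 2823 genes there. The 166 had been selected by p on the same arrays, which favours both outcomes, so these are no independent support. Leaving out biofilm 8, planktonic 8 or planktonic 9 left 0, 1 and 14 calls, and leaving out biofilm 9 gave 445.

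Differences depended on a gene's level and length. Outside the discordant blocks the median log2 difference was 0.75 in the lowest decile of levels and -0.10 in the highest, and -0.09 for genes up to 400 bp and 0.28 for those over 1500 bp. The trend was present in both culture numbers, and the difference between the planktonic arrays lay between 0.06 and 0.14 in every decile. It was steeper between the arrays numbered 8, from 0.978 in the lowest decile to -0.215 in the highest. Between those numbered 9 it ran from 0.668 to 0.0415. The 2 biofilm arrays thus also differed from each other along the level, so arrays of 1 culture type were not free of such a trend. Of the 155 genes that passed higher in biofilm outside the blocks, 110 had a level below the 25th percentile, and their median coding length was 1437 bp against 885 bp for genes that did not pass. Over all named genes, differences that kept their sign could still shrink with the trend removed. They went from 1.66 to 0.15 for htpG and from 1.20 to 0.16 for purA, against 2.40 to 1.62 for guaB. With the trend removed outside the blocks, median log2 differences of the lists were 0.09 for flagella, 0.14 for chemotaxis, 0.21 for electron transport, 0.03 for carbon uptake and -0.02 for fimbriae. The unadjusted camera p was then 0.00592 for electron transport, against 0.0391 outside the blocks before removal, 0.0396 for chemotaxis, 0.0538 for flagella, 0.328 for carbon uptake and 0.748 for fimbriae. Purine and pyrimidine synthesis was the 1 list that passed camera with Benjamini-Hochberg adjustment after removal, on the planktonic side, with a median of -0.35 over its 10 members outside the blocks and an adjusted p of 0.0430, against 0.250 before removal. With an estimated correlation it did not pass there, with an unadjusted p of 0.0780 and an adjusted p of 0.876 in camera with Benjamini-Hochberg adjustment. At the preset correlation the adjusted p of camera with Benjamini-Hochberg adjustment was 0.0833 for electron transport. It was also 0.0833 for aromatic amino acid synthesis and for translation factors and tRNA synthetases, and 0.0902 for branched-chain amino acid synthesis.

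**Figure D4:**
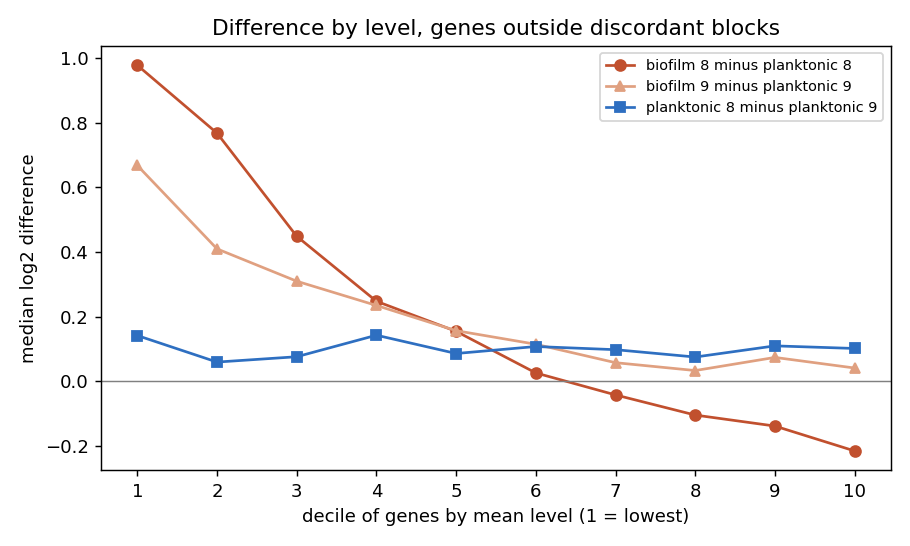
Median log2 difference (vertical axis) by decile of genes ordered by mean level (horizontal axis, 1 is the lowest), for genes outside discordant blocks. Biofilm minus planktonic falls from 0.98 to -0.22 between the arrays numbered 8 and from 0.67 to 0.04 between those numbered 9, while planktonic 8 minus planktonic 9 stays between 0.06 and 0.14. The difference between the biofilm arrays, which also depends on level, is not drawn.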

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

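The settings that leave out discordant blocks, set their values missing, remove the level and length trend or include unnamed probes were chosen after seeing the data, as were their combinations; the others were planned. The count of 0 genes between biofilm and planktonic cultures stayed 0 in limma under every planned normalization, floor, filter and variance model, and with all probes. At an adjusted p under 0.1 the count was 0 for the values as deposited and 5 with the floor at the 10th percentile. At an unadjusted p under 0.05 the count as deposited was 588. Leaving out 1 array gave 0 to 154 genes, the 154 (66 higher, 88 lower) without biofilm 8, where the lone biofilm array was the one with the most discordant blocks. In such fits the lone array is assumed to vary like the other group. Without discordant blocks of biofilm 9 alone the count was 0 of 3357 genes (lowest adjusted p 0.175 by limma with Benjamini-Hochberg adjustment). Without discordant blocks of any array it was 166, with the replicate block there 238 (165 shared), and with discordant values missing 326 of 3905 genes testable (285 higher, 41 lower). Leaving out 1 array outside the blocks gave 0 to 445. Among genes at an unadjusted p under 0.05, higher and lower numbered 510 and 78 as deposited, 245 and 173 after quantile normalization, 282 and 195 after cyclic loess, and 431 and 156 after median centring, which moved the median difference of all genes from 0.10 to -0.02. The replicate block left 0 genes and 0 lists passing. The deviations of equally numbered arrays correlated at 0.033 across genes, and the labels do not say that a number pairs arrays. No value was 0 or below, so leaving such values missing gave nothing to compare.

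The count of 0 lists became 3 with replicate block and quantile normalization (ribosomal proteins, hibernation and starvation, and prophage genes, all down), 1 without biofilm 9 (prophage genes, down) and 0 without any other array. With the correlation estimated per list, none of these passed. That alternative was planned for the main comparison and run in these settings after seeing the data. Unadjusted p for the 3 were 0.348, 0.203 and 0.451 (camera, lowest adjusted p 0.9205 after Benjamini-Hochberg adjustment). Outside discordant blocks it became 1 with the trend removed (purine and pyrimidine synthesis, down) and 2 with cyclic loess (ribosomal proteins down, translation factors up). With an estimated correlation these did not pass either, with unadjusted p of 0.0780, 0.203 and 0.245, and the count of lists was 0 in every setting run. The 253 genes at least 2-fold apart the same way became 116 after quantile normalization, 123 after cyclic loess, 84 with a floor, 36 with a pseudocount, 37 and 4 with filters at the 25th percentile and the median, 154 outside discordant blocks, 68 with the trend removed and 37 with both. The cause of these moves was not tested.

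None of the 24 genes chosen by p reversed under any setting run that included it. However, 11 on the biofilm side and 5 on the planktonic side lay in discordant blocks. These were absent wherever the discordant blocks of any array were left out. Choosing genes by p on the same arrays also makes reversals unlikely. Reversals among the other named genes follow as log2 differences. After quantile normalization, with or without the replicate block, csgA was at -0.33, fimA at -0.85, fliC at -0.069, fimG at -0.066 and uspA at -0.26. After cyclic loess csgA was at -0.31 (-0.32 outside discordant blocks), fimA at -0.83 (-0.81), fliC at -0.046 (-0.053), fimG at -0.094 (-0.073), uspA at -0.23 (-0.22) and csgF at -0.24 (-0.22). With arrays centred on their median csgA was at -0.093 and fimA at -0.074, and with a pseudocount fimA was at -0.011. Leaving out 1 array took csgA from -0.33 (without planktonic 9) to 0.39, csgD from -0.64 to 0.13 (without planktonic 8) and fimA from -0.57 (without planktonic 9) to 0.67, and without biofilm 8 they were at -0.016, 0.053 and -0.095. With the level and length trend removed serC was at -0.15, csgA at -0.065, fimA at -0.79, fliC at -0.34, csgF at -0.080, fimH at -0.021, pgaA at -0.29, bcsC at -0.29, lsrD at -0.047 and ptsG at -0.27, and those of them outside discordant blocks had the same values there. The cause was not tested.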

Other observations

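All the tests in this part were chosen after the results they concern had been seen. Genes of insertion sequences, mobile elements present in several copies on the chromosome, stood out among the brighter probes. Outside discordant blocks all 10 insH copies read higher in biofilm in both culture numbers, with mean intensities of 114 in biofilm and 60.6 in planktonic cells and log2 differences of 0.63 to 1.30. The 5 insD copies had 59.5 and 27.3, with differences of 0.72 to 2.40, the 6 insB copies 36.3 and 23.7, and the 5 insF copies 55.3 and 34.1. These 4 families stayed higher under quantile, median, 75th percentile and cyclic loess scaling and after trend removal. The short genes insA and insC, which belong to the same elements as insB and insD, had medians of -0.01 and -0.17, signs that turned with trend removal and, for insA, with 75th percentile and cyclic loess scaling. Copies outside discordant blocks passed limma with Benjamini-Hochberg adjustment, over the 2824 genes there, for 5 of 5 insD, 5 of 10 insH, 2 of 6 insB and 1 of 5 insF genes. Transcripts of near-identical copies can bind each other's probes, so these values cannot be assigned to single copies.

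Copies of the same insertion sequence gene also served to check probe names: the pooled SD of log2 level within 9 families was 0.868, against a median of 1.47 for random groups of genes, and 0 of 10000 random draws were as small (permutation p = 0.0001, the smallest they can give). Copies of some families still lay far apart, with insL from the 2.2 to the 96.8 percentile of levels, insD from 45.4 to 92.2 and insF from 38.3 to 88.2. The check covers insertion sequence genes only. Genes that textbooks call abundant were not all bright: ompA lay at the 8.01 percentile, lpp at 20.6 and ompC at 23.2. The 54 ribosomal protein genes had a median of 41.6, while rpsA lay at 65.5, rplL at 83.3 and tufA, which has a near-identical copy, at 93.7. Whether every intensity reflects the named gene thus stayed open.

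In biofilm 9, every second block between probes 1633 and 3072 disagreed with the other arrays. In the 7 blocks lying between the discordant ones biofilm 9 correlated with another array at 0.946 or more. Probe order partly followed gene class, however. Blocks discordant on any array held all 8 histidine synthesis genes and 22 of 33 translation genes, but 2 of 41 flagellar genes. The agreement in the blocks between therefore cannot by itself exclude changed transcripts in that culture. A candidate explanation is that signal of the preceding block was read or recorded at these probes: what remained of biofilm 9 after fitting the other arrays' mean correlated with that mean exactly 1 block earlier at 0.576 on average, against 0.137 at the best of the other offsets. For planktonic 8 the same correlation was 0.127, below the 0.211 found at another offset, so for that array a smaller share of such signal and other array faults cannot be told apart. Its discordant blocks alternated as well: they were every second block between probes 3169 and 4224, and in the blocks between them it correlated with another array at 0.972 to 0.985. How these blocks came to disagree was not tested.

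Dim and long genes read higher in biofilm. A single scale factor per array from the authors' normalization would shift all levels alike, whereas the lowest decile of levels exceeded the highest by 0.854 (bootstrap 95% interval over genes 0.781 to 0.999). The comparison restates the trend described above, and its interval does not measure the spread between arrays. If copies of an insertion sequence gene read the same transcripts, changed transcript levels alone would give them the same change. Within families, however, the change on the arrays of either number went with a lower level on the arrays of the other. The correlations were -0.489 and -0.72 (permutation p = 0.0026 and 0.0011, across 46 copies that are not independent). Copies of some families lay far apart in level, so whether they read the same transcripts is open. The test bears on these genes and not on others, and cannot decide even for them. Genomic DNA carried over with the biofilm RNA may contribute: insertion sequence genes exceeded 50 other genes of like length and level by a mean of 0.480 over 6 elements (exact sign-flip p = 0.0312, the smallest that 6 elements can give). The other genes excluded insertion sequence, rhs and tra genes, but were not otherwise checked to be single-copy. By gene family the excess was above 0 in 8 of 9, and insE, pooled with insF in its element, had -0.169. Genes of the same element differed, with 0.224 for insA against 0.675 for insB, and 0.0655 for insC against 1.25 for insD. More transcription of these elements in biofilm would give the same excess. A true difference between culture types stays open for these genes, and open and untested for all others.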
